A study of Homo sapiens with 96 samples.

How the data were processed

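The study measured polyadenylated RNA with a stranded library kit (TruSeq) in 96 libraries, 8 from each of 12 groups, from H9 human embryonic stem cell derivatives. Each of 6 sequencing runs held 16 libraries, with 1 or 2 of every group, so run and group are not confounded. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq, checked with FastQC 0.11.8 and MultiQC 1.0, quantified with Salmon 1.3.0 and normalized with DESeq2 1.30.0, with GRCh38 as genome build. The annotation release is not given in the sources used here. The deposited table holds 58434 genes by 96 libraries under versioned Ensembl identifiers. Its unit is a signal made by the authors by dividing gene counts by 1 size factor per library, with whole reads recovered here from each column. In every column 100% of the positive values were whole multiples of the smallest step within 0.001 read. In 6 libraries the step lay within 1.2% of 1, so that the deposited and the recovered values nearly coincide there.

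Recovered reads ranged from 9.49 to 29.63 M (megareads) per library (median 18.94 M), which leaves genes with values under about 10 with a large counting error. Deposited totals of the 88 day 10 libraries were 18.11 to 18.99 M except 20.95 M in methyl mercury IC20/100 replicate 8. Symbols were found for 58087 genes, and positions and biotypes for 58171 from GENCODE 29, which is matched by identifier and is not known to be the release the authors used. Within groups, 336 pairs of libraries were compared by chi-square on recovered reads to look for duplicated libraries, and 0 pairs differed by no more than counting error (lowest chi-square per degree of freedom 16.6, median 22.3). No library was left out of the main comparisons.

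The comparisons, the planned tests, the gene lists and the rule for named genes were fixed before the data were examined. The planned test was edgeR quasi-likelihood with TMM scaling and its own filter on low counts, with limma on log2 values and the same terms in its place if the table held normalized values. The table does, so limma 3.58.1 (R 4.3.3) with a trended prior was used on log2 of the deposited value plus a pseudocount of 2, without further scaling. The pseudocount and the filter values for this case were set after the table was seen. Genes with a value of at least 10 in at least 8 libraries of the fit were kept. Differentiation was tested on the 16 NPC and control libraries (18063 genes, 9 residual degrees of freedom). Exposures, the direct comparisons of concentrations and the pairs of compounds were tested in 1 fit of the 88 day 10 libraries (20136 genes, 72 residual degrees of freedom). Group and sequencing run were the terms of both fits. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and the calls of at least 1.5-fold were also counted. All exposed groups were compared with the same 8 controls, so their comparisons are not independent. With run kept, libraries matched best with their own replicate number in 5 of 8 cases for chlorpyrifos IC5 and 6 of 8 for fluoxetine IC20/100. These groups share the run of each number with the controls. With run removed this was 0 for both, but removing run there also removes most of any pairing. These groups therefore cannot tell pairing from run. Over all comparisons, the highest median correlation of same-numbered deviations with run removed was 0.125 (differentiation), against 0.082 for other numbers. Where number and run could be told apart, replicate numbers therefore hardly paired libraries, and no pairing was used. Salmon, FastQC and the reads themselves were not used here.

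The 28 gene lists held 588 entries, all found in the table. Each list was tested with camera of limma, which compares its genes with all other genes, at a preset correlation of 0.01 and with run as a term. P-values were adjusted over the 308 tests against a reference group and over the 140 tests between concentrations, the latter added to the plan. Of these, 108 (35 up, 73 down) and 36 (23 up, 13 down) passed, and 61 and 20 of them passed with the correlation between genes estimated from the data. The rule for named genes takes the largest rises and falls among called protein-coding genes of at least 1.5-fold and a mean of at least 5 CPM, 10 each way for differentiation, 8 at IC5 and 4 at IC20/100. It adds up to 4 called members of each list that passed and up to 2 of other lists, and in every comparison NES, SOX2, MKI67, DCX, MAP2, GFAP and S100B. The rule names more genes than the text holds, and the selection among them was made after their values were seen. Some genes that the rule names are not reported here. Genes that a text passage names outside the rule are marked as chosen after their values were seen.

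For the differentiation score, run was removed from the log2 values and the mean of the genes lower in controls than in NPC was subtracted from the mean of those higher. Groups were compared by an exact permutation test over all 495 splits of 8 against 4 libraries, 2-sided, adjusted over the 10 groups. For the shared response, the 8 controls were split into 4 and 4 in all 35 ways, and the correlations averaged. On simulated data, with 50 genes changed at each size, the differentiation test recovered 26, 70, 96 and 94% of changes of 1.2, 1.5, 2 and 3-fold and called 8 unchanged genes, and the exposure test recovered 46, 82, 88 and 98% and called 12. Also computed, as fixed beforehand, were another scaling (TMM), DESeq2 1.42.0 on the recovered reads, no filter, no run term, a replicate block, a test against a 1.2-fold change, a fragment size term, each control left out in turn, and other sets of groups in the fit. Chosen after seeing the data were edgeR 4.0.16 on the recovered reads, pseudocounts of 0.5 and 8, and fits without NPC replicate 6, methyl mercury IC20/100 replicate 8, methyl mercury IC5 replicate 4, valproic acid IC5 replicate 4, or valproic acid IC20/100 replicates 4 and 8.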

Results

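Polyadenylated RNA was sequenced from 96 libraries made from derivatives of H9, an established human embryonic stem cell line. The libraries fall into 12 groups of 8. One group was neural progenitor cells (NPC, day 0), and the other 11 groups were neuron and astrocyte co-cultures grown from such cells and sampled on day 10. Of the day 10 groups, 1 was an unexposed control and 10 were exposed to acrylamide, chlorpyrifos, fluoxetine, methyl mercury or valproic acid. Each compound was given at 2 concentrations named IC5 and IC20/100, read here as the concentration with 5% inhibition and the 20% one diluted 100-fold. The molar concentrations and the length of exposure are not given in the sources used here. Acrylamide and valproic acid were dissolved in medium, and the other compounds in dimethyl sulfoxide (DMSO), at 0.25% in the final medium. Whether the unexposed controls held DMSO is not given in the sources used here. For the compounds in DMSO, an effect of the vehicle therefore cannot be told apart from one of the compound in comparisons with controls. All 8 libraries of a group are technical replicates of 1 experiment, so each p-value measures only the spread between such replicates. The recovered reads per library ranged from 9.49 to 29.6 M (megareads), with a median of 18.9 M. Values are the deposited normalized read counts, given as mean ± SD of 8 libraries. Log2 fold changes, given ± SE, were fitted on log2 of the value plus 2, which understates the change of genes with low values. Adjusted p-values are from limma, and gene positions are on GRCh38.

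To determine what changed as progenitors became day 10 co-cultures, unexposed controls were compared with NPC. FABP7, a fatty acid binding protein of radial glia (ENSG00000164434.12, chromosome 6, 122779475 to 122784074), fell from 19190 ± 989 to 3328 ± 93.0, a log2 fold change of -2.53 ± 0.03 (adjusted p = 1.29e-13). MKI67, a marker of dividing cells, fell from 8230 ± 572 to 3210 ± 243 (-1.36 ± 0.06, adjusted p = 1.65e-09). SLC32A1, the vesicular GABA transporter (ENSG00000101438.4, chromosome 20, 38724462 to 38729372), rose from 6.73 ± 2.73 to 183 ± 12.9 (4.43 ± 0.15, adjusted p = 2.48e-10). PRDM13, a transcriptional regulator of inhibitory neuron fate (ENSG00000112238.11, chromosome 6, 99606730 to 99615578), rose by 5.80 ± 0.17 on the log2 scale. The connexin gene GJA4 (ENSG00000187513.9, chromosome 1, 34792998 to 34795747) had a value of 3488 ± 192 in NPC and 0.365 ± 0.507 in controls, too few reads for a firm fold. PAX8, a paired box transcription factor, fell from 3910 ± 132 to 91.3 ± 31 (-5.47 ± 0.17).

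All 28 measured cell cycle genes fell, among them RRM2 (-2.63 ± 0.10) and E2F1 (-1.96 ± 0.08). The list passed camera (adjusted p = 7.04e-11) but not with an estimated correlation (adjusted p = 0.108). Of 24 measured genes of neurogenesis and young neurons, 18 rose and 4 fell (19 and 4 adjusted over the list alone; camera adjusted p = 0.00253), with DCX, a microtubule protein of young neurons, up by 0.74 ± 0.04 and NEUROG2, a proneural factor, by 1.72 ± 0.09. With an estimated correlation the adjusted p was 0.141. Among 32 mature neuron and synapse genes, 23 rose and 7 fell, the same counts as adjusted over the list alone. The glutamate receptor genes GRIN1 (2.73 ± 0.37) and GRIN2B (2.41 ± 0.17) rose, whereas MAP2 had 17970 ± 955 against 16960 ± 1070 in NPC (0.08 ± 0.04, adjusted p = 0.126). Camera gave this list an adjusted p of 0.000371, and 0.0729 with an estimated correlation. Of 16 transmitter identity genes, 10 rose and 3 fell (camera adjusted p = 0.0333, and 0.0873 with an estimated correlation). The GABA-synthesizing enzyme gene GAD2 rose by 3.81 ± 0.33 and SLC18A3, the vesicular acetylcholine transporter, fell from 427 ± 26.4 to 36.9 ± 4.31 (-3.49 ± 0.08). NES, an intermediate filament of neural stem cells, fell by 0.89 on the log2 scale (SE 0.04), while SOX2, a stem cell transcription factor, rose by 0.40 ± 0.04. The progenitor list as a whole had 7 genes up and 14 down of 24 and did not pass (camera adjusted p = 0.26).

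Astrocyte markers moved both ways, 10 up and 6 down of 20 (camera adjusted p = 0.206). GFAP was low, 25.7 ± 14.6 against 9.70 ± 10.2 (1.48 ± 0.45, adjusted p = 0.0115, higher in 5 of 6 sequencing runs). The NPC value rests in part on replicate 6, at 34.5 against 2.12 to 8.94 in the other 7 libraries. Without it the NPC value was 6.15 ± 2.22 and the log2 fold change 1.89 ± 0.38 on the same genes, though GFAP then no longer met the low-value filter. S100B fell from 74.4 ± 9.02 to 19.4 ± 3.34 (-1.81 ± 0.13). Mesenchymal and pericyte genes fell, 10 of 13 with 1 up (camera adjusted p = 0.00258, and 0.0289 with an estimated correlation), with COL1A1 at -3.72 ± 0.25. Hypoxia and glycolysis genes were the other list that passed both ways, with 15 up and 3 down of 20 (camera adjusted p = 0.00497, and 0.0367 with an estimated correlation). VEGFA (2.36 ± 0.05) and BNIP3 (1.84 ± 0.04) rose, while ADM (-4.88 ± 0.15) and the glucose transporter gene SLC2A1 (-3.50 ± 0.05) fell. Cholesterol synthesis genes fell, 22 of 25 with 1 up (camera adjusted p = 1.51e-05, and 0.0501 with an estimated correlation). The integrated stress and unfolded protein response list had 16 genes up and 5 down of 24, with DDIT4, an inhibitor of mTOR signalling, up by 3.32 ± 0.04 (camera adjusted p = 0.00887, and 0.488 with an estimated correlation). Over 18063 genes tested, 6126 were higher and 6644 lower, of which 3685 and 3338 changed at least 1.5-fold. All genes named in the text as changed moved the same way in all 6 runs unless stated.

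**Figure D1:**
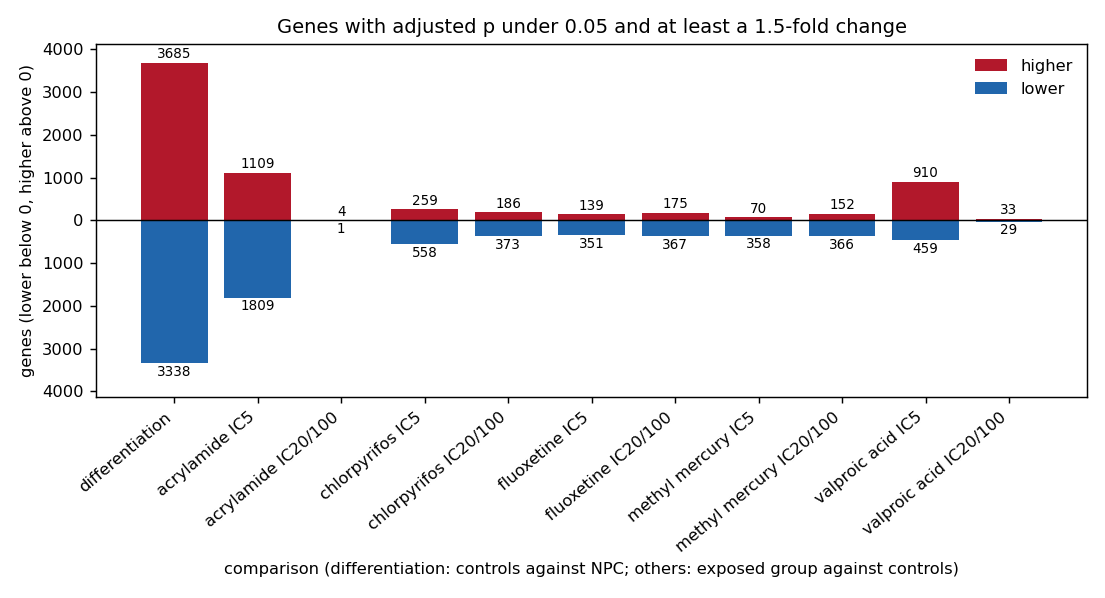
Number of genes with an adjusted p under 0.05 and at least a 1.5-fold change in each comparison, higher above the zero line and lower below it. Among the exposed groups the counts were highest for acrylamide IC5, 1109 higher and 1809 lower, and lowest for acrylamide IC20/100, 4 higher and 1 lower.

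To determine what each exposure changed, each exposed group was compared with the 8 unexposed day 10 controls. Acrylamide at IC5 was accompanied by lower stress-response, hypoxia and transmitter identity transcripts and by higher cell cycle transcripts. CEBPB, a transcription factor of the stress response (ENSG00000172216.5, chromosome 20, 50190734 to 50192689), fell from 124.1 ± 21.5 to 14.6 ± 3.80 (-2.95 ± 0.13, adjusted p = 1.40e-31). BNIP3, a hypoxia-induced gene of mitophagy (ENSG00000176171.11, chromosome 10, 131966455 to 131982013), fell from 2497 ± 133 to 918 ± 52.6 (-1.45 ± 0.05, adjusted p = 3.86e-39). STC2, a secreted glycoprotein hormone, fell from 776 ± 250.0 to 48.6 ± 21.9 (-3.99 ± 0.26). The largest rises included WFIKKN1, which encodes a secreted protease inhibitor, from 20.9 ± 5.48 to 141 ± 17.6 (2.65 ± 0.16, adjusted p = 4.69e-24), and NQO1, an oxidative stress enzyme, from 112 ± 9.13 to 368 ± 26.5 (1.70 ± 0.11). The dopamine-synthesizing enzyme gene TH fell from 818 ± 73.2 to 304.5 ± 14.4 (-1.41 ± 0.09).

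Of 24 genes of the integrated stress and unfolded protein response, 18 fell and 2 rose at acrylamide IC5 (18 and 3 adjusted over the list alone; camera adjusted p = 1.78e-17), with TRIB3 at -2.35 ± 0.13, CHAC1 at -2.29 ± 0.11 and ATF5 at -2.29 ± 0.10. Hypoxia and glycolysis genes fell, 16 of 21 with 1 up (camera adjusted p = 3.11e-13), among them P4HA1, a collagen hydroxylase (-1.37 ± 0.06), and EGLN3, an oxygen sensor (-1.59 ± 0.17). Cell cycle genes rose, 25 of 28 (27 adjusted over the list alone; camera adjusted p = 2.13e-14), among them RRM2 (1.18 ± 0.12), MCM5 (0.93 ± 0.09) and MKI67 (0.65 ± 0.07). Cholesterol synthesis genes fell, 18 of 25 with 4 up (19 and 4 adjusted over the list alone; camera adjusted p = 1.32e-07), with MSMO1 at -0.94 ± 0.06. Transmitter identity genes fell, 9 of 21 with 1 up (camera adjusted p = 0.029), GAD2 by 1.47 on the log2 scale (SE 0.26). These lists also passed with an estimated correlation. Of 32 mature neuron genes, 16 fell and 3 rose, GRIA2, an AMPA receptor subunit, at -0.90 ± 0.10 (camera adjusted p = 0.0124, and 0.063 with an estimated correlation). Heat shock genes were 9 up and 2 down of 14, with the chaperone gene HSPA8 at 0.68 ± 0.05 (camera adjusted p = 0.000266, and 0.078 with an estimated correlation). All 10 mitochondrially encoded genes that passed, of 13, rose (camera adjusted p = 2.15e-08, and 0.0969 with an estimated correlation). The share of reads from such genes was 3.09 ± 0.14% against 2.47 ± 0.10% in controls. S100B rose by 1.33 ± 0.16. In total 4119 genes were higher and 4332 lower of 20136 tested.

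At acrylamide IC20/100, 12 genes differed from controls by limma, 10 higher and 2 lower, of 1324 with an unadjusted p under 0.05. HK2, a glycolytic hexokinase (ENSG00000159399.9, chromosome 2, 74833981 to 74893359), rose from 1570 ± 80 to 1867 ± 109 (0.25 ± 0.04, adjusted p = 0.00142). CHAMP1, a chromosome alignment protein, rose by 1.04 ± 0.20 (adjusted p = 0.00513). GDF1 was also called, but it overlaps CERS1 on the same strand and its value is uncertain. Hypoxia and glycolysis genes had 1 up of 21 (5 adjusted over the list alone; camera adjusted p = 7.27e-06, and 0.0224 with an estimated correlation). The count of 12 was 25 by DESeq2, 8 by edgeR, 27 without methyl mercury IC20/100 replicate 8, 6 without control replicate 4 or 6, 7 without control replicate 1, and 0 in a fit of only the 16 libraries compared. Directly compared, the IC5 cultures had 4028 genes higher and 4256 lower than the IC20/100 cultures. In that test 26 of 28 cell cycle genes were higher at IC5 (camera adjusted p = 5.08e-15), and 16 of 21 hypoxia genes lower (camera adjusted p = 4.59e-17). Both lists passed with an estimated correlation.

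Chlorpyrifos at both concentrations was accompanied by lower stress-response and p53 target transcripts. At IC5, SLC7A11, a cystine transporter induced by oxidative stress (ENSG00000151012.13, chromosome 4, 138164097 to 138242349), fell from 728 ± 129 to 136 ± 15.5 (-2.38 ± 0.13, adjusted p = 6.97e-26), and CHAC1, a glutathione-degrading enzyme, from 373 ± 61.6 to 87.9 ± 10.5 (-2.05 ± 0.11). CDKN1A, the cell cycle inhibitor p21, fell from 2236 ± 465 to 738 ± 95.3 (-1.58 ± 0.13). Higher values were found for CPT1A, the carnitine palmitoyltransferase of fatty acid oxidation (ENSG00000110090.13, chromosome 11, 68754620 to 68844410), at 598 ± 109 against 295.5 ± 49.3 (1.01 ± 0.13, adjusted p = 3.24e-09), and for AMH, a hormone of the TGF-beta family, at 1171 ± 77.1 against 608 ± 68.4 (0.95 ± 0.08). TH fell to 445.5 ± 95.6 (-0.89 ± 0.09).

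Of the 24 integrated stress and unfolded protein response genes, 20 fell at chlorpyrifos IC5 and 0 rose (camera adjusted p = 3.05e-48), and of 20 p53 targets 15 fell and 1 rose (16 and 1 adjusted over the list alone; camera adjusted p = 1.73e-17). Both lists passed with an estimated correlation, as did progenitor genes, 7 down and 3 up of 24 (camera adjusted p = 0.0115), with FABP7 at -0.80 ± 0.07 and LIN28A, an RNA-binding protein of early progenitors, at -0.79 ± 0.07. Metallothionein and metal genes were 3 up of 7 (camera adjusted p = 0.022), MT2A by 1.22 ± 0.19. Cell cycle genes were 14 up and 1 down of 28, with PCNA at 0.52 ± 0.07 (camera adjusted p = 3.56e-07, and 0.122 with an estimated correlation). At IC20/100, 18 stress-response genes (22 adjusted over the list alone) and 15 p53 targets (16 adjusted over the list alone) fell, with CEBPB at -1.94 ± 0.13 and CDKN1A at -1.45 ± 0.13 (camera adjusted p = 2.66e-53 and 6.70e-21). Cell cycle genes there were 11 up and 1 down (camera adjusted p = 0.00038, and 0.28 with an estimated correlation). Mature neuron genes were 7 down and 1 up of 32 (camera adjusted p = 0.00739), and transmitter identity genes 5 down of 21 with TH at 405.5 ± 36.7 against 818 ± 73.2 (camera adjusted p = 0.022). These lists passed with an estimated correlation except cell cycle.

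The counts were 1998 genes higher and 1964 lower at chlorpyrifos IC5 (259 and 558 by at least 1.5-fold), and 1422 higher and 1414 lower at IC20/100 (186 and 373). Between the concentrations 10 genes differed, 8 higher and 2 lower at IC5. CPT1A differed most, 598 ± 109 at IC5 against 150.0 ± 11.7 at IC20/100 (1.98 ± 0.13, adjusted p = 2.76e-20). NEFL, a neurofilament subunit, was higher by 0.17 ± 0.03 (adjusted p = 0.0103). The mature neuron list was higher at IC5, with 1 gene called of 32 (6 adjusted over the list alone; camera adjusted p = 4.62e-08, and 9.24e-05 with an estimated correlation). Other tools gave 63 (DESeq2) and 16 (edgeR) genes between the concentrations, 27 were called without methyl mercury IC20/100 replicate 8, 5 with no run term and 2 in a fit of only the 16 libraries compared.

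Fluoxetine at IC5 was accompanied by higher cholesterol synthesis and lysosome transcripts. The sterol enzyme genes MVD (ENSG00000167508.12, chromosome 16, 88651935 to 88663161; 2432 ± 376 against 1187 ± 206; 1.09 ± 0.12, adjusted p = 2.54e-11) and DHCR7 (0.91 ± 0.09) rose. Of 25 cholesterol synthesis genes 20 rose and 0 fell (21 adjusted over the list alone; camera adjusted p = 2.22e-31). Lysosome genes rose, 11 of 23 (14 adjusted over the list alone; camera adjusted p = 2.77e-08), among them NPC2, a lysosomal cholesterol carrier (0.52 ± 0.09), and MCOLN1, a lysosomal calcium channel (0.57 ± 0.12). ADRA2A, an adrenergic receptor, rose from 62.7 ± 8.58 to 147 ± 12.4 (1.23 ± 0.09, adjusted p = 5.38e-19).

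SLC7A11 fell to 90.3 ± 17.2 (-3.04 ± 0.13, adjusted p = 4.71e-32). Stress-response genes fell, 18 of 24 (camera adjusted p = 3.38e-59), and p53 targets, 13 of 20 (14 adjusted over the list alone; camera adjusted p = 1.58e-16). WNT pathway genes fell, 6 of 25 with 0 up (6 and 1 adjusted over the list alone; camera adjusted p = 0.00278), among them SFRP1, a secreted WNT regulator (-0.52 ± 0.06), and WNT7B (-0.38 ± 0.04). Axon guidance genes fell, 13 of 30 with 2 up (camera adjusted p = 1.32e-06), the netrin receptor gene UNC5A by 1.26 on the log2 scale (SE 0.13). Progenitor genes were 9 down and 2 up of 24 (11 and 2 adjusted over the list alone; camera adjusted p = 0.000238). All 7 lists named for fluoxetine IC5 passed with an estimated correlation. CYP26B1, which degrades retinoic acid, fell from 860 ± 80.5 to 324 ± 72.7 (-1.37 ± 0.15).

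At fluoxetine IC20/100 the stress-response list again had 18 of 24 genes down (camera adjusted p = 3.35e-50), with CHAC1 at -1.96 ± 0.11, and the p53 list 13 of 20 (15 adjusted over the list alone; camera adjusted p = 1.88e-19). Progenitor genes were 11 down and 5 up of 24 (camera adjusted p = 0.000192), LIN28A at -0.90 ± 0.07. All 3 lists passed with an estimated correlation. Cell cycle genes were 12 up and 1 down of 28 (camera adjusted p = 5.82e-05, and 0.224 with an estimated correlation). The cholesterol synthesis list did not pass there (camera adjusted p = 0.0854, 2 up and 8 down). Tested directly, 22 of 25 cholesterol synthesis genes were higher at IC5 than at IC20/100 (24 adjusted over the list alone; camera adjusted p = 8.58e-69), DHCR7 by 0.79 ± 0.09. Also higher at IC5 were 7 of 23 lysosome genes (12 adjusted over the list alone), 9 of 21 hypoxia genes, and 6 of 14 mesenchymal genes with the collagen gene COL3A1 at 1.03 ± 0.13. Outside these lists BHLHE40, a circadian and hypoxia-responsive repressor, was higher at IC5 by 1.22 ± 0.17. Cell cycle genes were lower, 11 of 28 (21 adjusted over the list alone). The camera adjusted p-values of these 4 lists were 1.45e-10, 2.06e-10, 3.11e-05 and 7.84e-17, and all 4 passed with an estimated correlation. The counts were 1102 higher and 1197 lower at IC5 (139 and 351 by at least 1.5-fold), 1385 higher and 1519 lower at IC20/100 (175 and 367), and 464 higher and 294 lower between the concentrations. Without methyl mercury IC20/100 replicate 8 the last count, 758 in all, became 1175, and in a fit of only the 16 libraries compared 450. In the fit without that methyl mercury library, fluoxetine IC5 had 1546 genes higher and 1538 lower than controls.

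**Figure D2:**
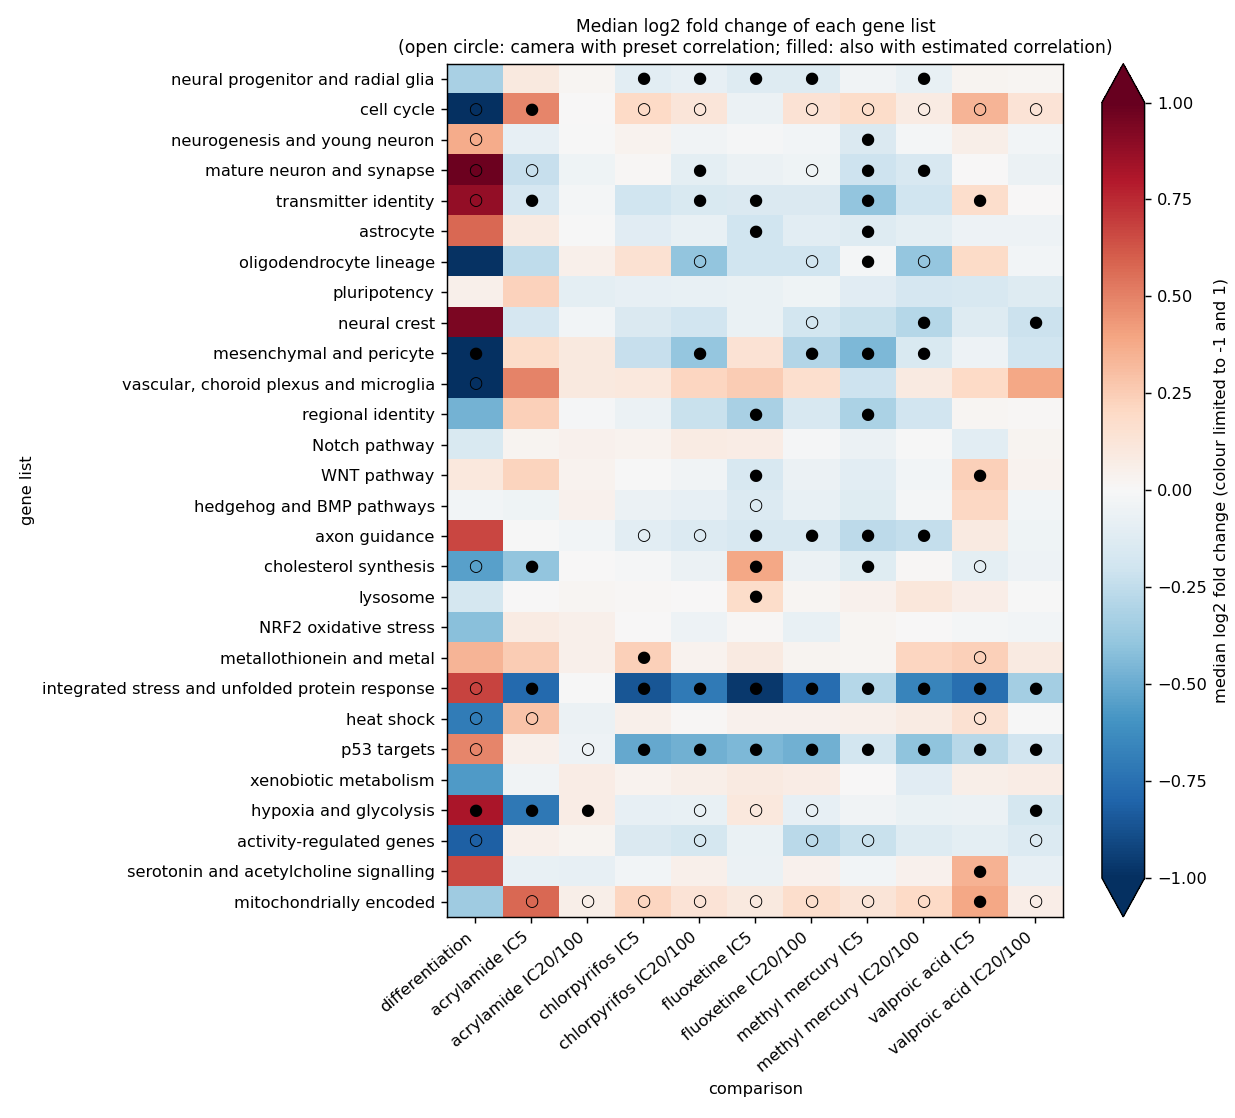
Median log2 fold change of each of the 28 gene lists (vertical axis) in each comparison (horizontal axis), as colour from -1 to 1. Open circles mark lists that passed camera with the preset correlation and filled circles those that also passed with an estimated correlation, 108 and 61 of 308 tests.

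Methyl mercury at IC5 was accompanied by lower transmitter identity, mature neuron and axon guidance transcripts. TH fell from 818 ± 73.2 to 337 ± 52.2 (ENSG00000180176.14, chromosome 11, 2163929 to 2171877; -1.28 ± 0.09, adjusted p = 2.75e-19), and FABP7 from 3328 ± 93.0 to 1375 ± 108 (-1.27 ± 0.07). CYP26B1 (ENSG00000003137.8, chromosome 2, 72129238 to 72148038) fell from 860 ± 80.5 to 262 ± 82.9 (-1.73 ± 0.15, adjusted p = 2.15e-15). ETV4, a transcription factor downstream of fibroblast growth factor signalling, fell from 144.5 ± 35.5 to 46.7 ± 15.2 (-1.59 ± 0.16), and SPRY4, an inhibitor of that signalling, from 291 ± 59.0 to 112 ± 18.0 (-1.34 ± 0.12). The proneural gene NEUROG2 rose from 181 ± 20.9 to 295.0 ± 26.9 (0.71 ± 0.07, adjusted p = 1.57e-13), and NEUROG1 by 0.66 ± 0.11.

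Transmitter identity genes fell, 10 of 21 with 0 up (camera adjusted p = 4.48e-09), among them SLC18A3 (-0.89 ± 0.15) and GAD2 (-0.84 ± 0.26). Mature neuron genes fell, 14 of 32 with 1 up (18 and 1 adjusted over the list alone; camera adjusted p = 1.47e-09), GRIN1 by 0.59 (SE 0.18) and the postsynaptic scaffold gene DLG4 by 0.38 (SE 0.05) on the log2 scale. Axon guidance genes fell, 15 of 30 with 1 up (18 and 1 adjusted over the list alone; camera adjusted p = 4.95e-12), ROBO3, a commissural axon receptor, at -0.60 ± 0.05. Of the stress-response genes, 16 of 24 fell and 2 rose (camera adjusted p = 2.43e-14), ATF5 at -0.87 ± 0.10. The p53 targets fell, 8 of 20 (12 adjusted over the list alone; camera adjusted p = 6.20e-06). Cholesterol synthesis genes fell, 8 of 25 with 1 up (11 and 1 adjusted over the list alone; camera adjusted p = 3.14e-05), and mesenchymal genes, 4 of 14 (camera adjusted p = 0.000432). These 7 lists passed with an estimated correlation. Cell cycle genes were 9 up of 28 (14 adjusted over the list alone; camera adjusted p = 2.44e-08, and 0.0929 with an estimated correlation). Replicate 4 of this group stood apart in this list and in the differentiation score, and without it 4 cell cycle genes were up, with a list median of 0.14 against 0.18. The metallothionein and metal list, with 1 gene up and 1 down of 7, did not pass (camera adjusted p = 0.84). In it MT2A, a metal-binding protein, rose by 0.60 ± 0.19 (higher in 5 of 6 runs) and MT3 fell by 0.58 (SE 0.18). The oxidative stress list, with 1 up and 3 down of 22, did not pass either (camera adjusted p = 0.862), and its median, 0.02, and mean, -0.01, differed in sign.

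At methyl mercury IC20/100, 18 stress-response genes of 24 and 12 p53 targets of 20 (14 adjusted over the list alone) fell (camera adjusted p = 1.92e-42 and 1.78e-15), with CHAC1 at -1.68 ± 0.11 and CDKN1A at -1.33 ± 0.13. Axon guidance genes were 12 down and 1 up of 30 (camera adjusted p = 9.95e-08) and mature neuron genes 9 down and 1 up of 32 (camera adjusted p = 0.00023). All 4 lists passed with an estimated correlation. Replicate 8 of this group stood apart, with 12.6% of its reads in ribosomal protein genes against 6.24 to 7.08% in the other 7 libraries. Without it the stress-response and p53 counts were again 18 and 12 down, and the axon guidance and mature neuron counts were 9 and 7 down. Between the concentrations, stress-response genes were higher at IC5, 18 of 24 (19 adjusted over the list alone; camera adjusted p = 1.38e-31), CEBPB with 75.1 ± 8.57 against 35.8 ± 8.73 (1.05 ± 0.13, adjusted p = 1.69e-08). SLC7A11, of the oxidative stress list, had 571 ± 115 against 217 ± 72.2 (1.43 ± 0.13). Also higher were 6 p53 targets of 20 (camera adjusted p = 4.19e-08), whereas 5 of 21 transmitter identity genes (camera adjusted p = 1.67e-06) and 8 of 25 cholesterol synthesis genes (camera adjusted p = 1.21e-07) were lower at IC5. The 4 lists passed with an estimated correlation, and without replicate 8 their counts were 19, 8, 4 and 6. The counts of genes were 976 higher and 1221 lower at IC5 (70 and 358 by at least 1.5-fold), 1654 higher and 1531 lower at IC20/100 (152 and 366), and 519 higher and 523 lower between the concentrations. In a fit of only the 16 libraries compared, 351 genes were called at IC20/100, 92 higher and 259 lower, and 27 between the concentrations, 19 higher and 8 lower, so the larger direction was not the same as in the main fit.

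Valproic acid at IC5 was accompanied by higher transmitter identity, serotonin and acetylcholine signalling, and WNT pathway transcripts. RPH3A, a synaptic vesicle protein (ENSG00000089169.15, chromosome 12, 112570380 to 112898881), rose from 113 ± 51.9 to 712 ± 116 (2.74 ± 0.25, adjusted p = 9.37e-15). SLC18A3 rose from 36.9 ± 4.31 to 93.2 ± 13.3 (1.29 ± 0.15, adjusted p = 5.20e-11) and ACHE, acetylcholinesterase (ENSG00000087085.15, chromosome 7, 100889994 to 100896974), from 179 ± 15.6 to 372 ± 46.4 (1.04 ± 0.12). Of 21 transmitter identity genes 8 rose and 0 fell (camera adjusted p = 0.00406), and of 17 serotonin and acetylcholine signalling genes 5 rose and 0 fell (camera adjusted p = 0.0124), HTR2C, a serotonin receptor gene, by 1.07 ± 0.15. WNT pathway genes were 10 up and 4 down of 25 (12 and 4 adjusted over the list alone; camera adjusted p = 0.00278), with SFRP1 at 0.70 ± 0.06 and TCF7 at 0.84 ± 0.15. NES rose from 15560 ± 995 to 21180 ± 642 (0.45 ± 0.04).

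Mitochondrially encoded genes rose, 12 of 13 (13 adjusted over the list alone; camera adjusted p = 3.19e-12), MT-CYB by 0.60 ± 0.05, and the share of reads from such genes was 3.05 ± 0.08%. Stress-response genes fell, 19 of 24 with 1 up (20 and 1 adjusted over the list alone; camera adjusted p = 7.04e-35), among them CHAC1 (-2.45 ± 0.11, adjusted p = 2.04e-30) and ATF5 (-2.40 ± 0.10). The p53 targets fell, 14 of 20 (camera adjusted p = 3.56e-07), CDKN1A from 2236 ± 465 to 1114 ± 209. The 6 lists named so far for this group passed with an estimated correlation. Cell cycle genes were 17 up and 1 down of 28, MKI67 at 0.43 ± 0.06 (camera adjusted p = 2.91e-07, and 0.118 with an estimated correlation). Metallothionein and metal genes were 4 up and 1 down of 7, MT1X at 2.05 ± 0.30 (camera adjusted p = 0.0256, and 0.0527 with an estimated correlation).

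At valproic acid IC20/100, hypoxia and stress-response genes were lower than in controls. P4HA1 fell from 1935 ± 182 to 1362 ± 192 (-0.53 ± 0.06, adjusted p = 4.00e-10) and VEGFA from 5798 ± 336 to 4207 ± 336 (-0.45 ± 0.05). Of 21 hypoxia genes 5 fell (8 adjusted over the list alone; camera adjusted p = 1.52e-10), of 24 stress-response genes 14 (18 adjusted over the list alone; camera adjusted p = 1.79e-26), and of 20 p53 targets 6 (9 down and 1 up adjusted over the list alone; camera adjusted p = 1.68e-08). These lists passed with an estimated correlation. Cell cycle genes were 8 up of 28, PCNA at 0.35 ± 0.07 (12 adjusted over the list alone; camera adjusted p = 1.90e-08, and 0.0905 with an estimated correlation). Replicates 4 and 8 of this group stood apart, and without both the counts were 4 hypoxia, 5 stress-response, 2 p53 and 0 cell cycle genes by limma, 7 of the last list having an unadjusted p under 0.05. The medians of these lists were then -0.12, -0.26, -0.13 and 0.04 against -0.18, -0.34, -0.20 and 0.14 with all libraries, and their unadjusted camera p-values 4.13e-11, 5.12e-23, 1.51e-06 and 0.00324. The count of all genes, 235 higher and 276 lower, fell from 511 to 93 without these 2 libraries, was 320 without control replicate 1, was 329 with no run term and 22 (4 higher, 18 lower) in a fit of only the 16 libraries compared, and was 925 without methyl mercury IC20/100 replicate 8. Directly compared, 1960 genes were higher and 1463 lower at IC5 than at IC20/100. Among them RPH3A was higher by 2.21 ± 0.25, SLC18A3 by 1.52 ± 0.15 and PMP2, a myelin fatty acid binding protein, by 1.99 ± 0.13 (adjusted p = 3.84e-21). Of the lists, 5 of 21 transmitter identity genes and 9 of 25 WNT pathway genes (1 down) were higher at IC5 (camera adjusted p = 0.00119 and 0.00209), and 19 of 24 stress-response genes were lower with 3 higher (camera adjusted p = 4.94e-26). All 3 passed with an estimated correlation.

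**Figure D3:**
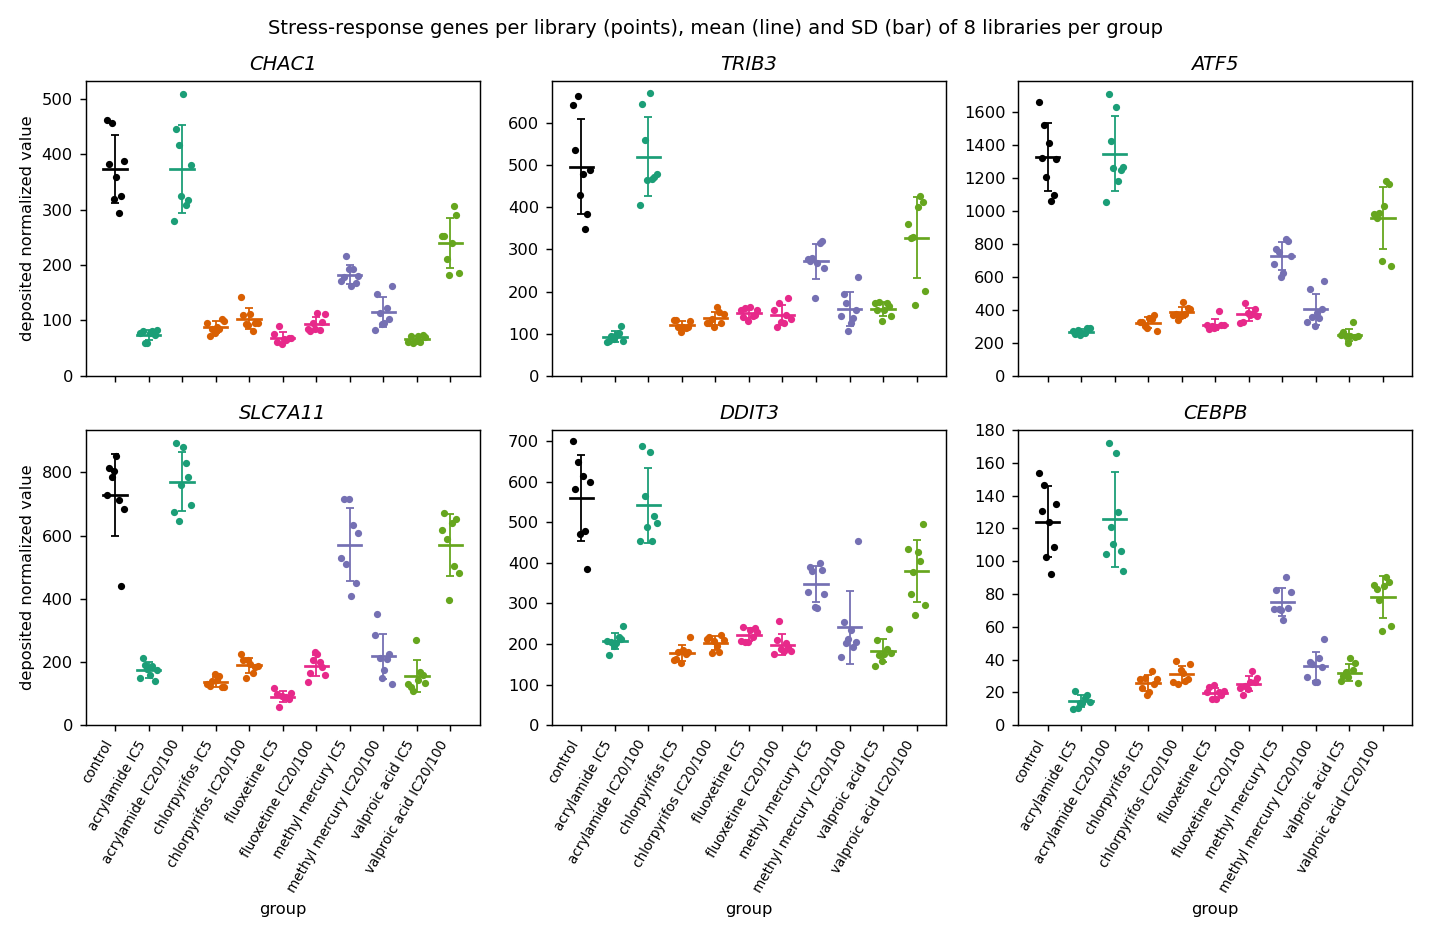
Deposited normalized values of CHAC1, TRIB3, ATF5, DDIT3 and CEBPB, of the stress-response list, and SLC7A11, of the oxidative stress list, in each day 10 library (points), with the mean (line) and SD (bar) of 8 libraries per group. CHAC1 had a mean of 373 in controls and 66.2 to 240 in the exposed groups other than acrylamide IC20/100.

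To determine how far the compounds differed from each other, the 10 pairs at IC5 were compared without the controls. The median number of genes with at least a 1.5-fold difference was 1383.5. It was lowest for chlorpyrifos against fluoxetine, 228, fluoxetine against methyl mercury, 281, and chlorpyrifos against methyl mercury, 371. The pairs with acrylamide gave 1514 (chlorpyrifos), 2175 (fluoxetine), 2236 (methyl mercury) and 2554 (valproic acid) genes. Valproic acid differed from chlorpyrifos by 1111, from fluoxetine by 1253 and from methyl mercury by 1526 genes.

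Log2 fold changes of different compounds were correlated across genes, each compound against 4 of the 8 controls and the other against the remaining 4. The median Pearson r over the 10 pairs was 0.283 at IC5 (0.095 to 0.437) and 0.231 at IC20/100 (0.051 to 0.41). In 100 simulated rounds of unchanged groups the split controls gave a median r of -0.03, with single rounds from -0.55 to 0.53. That range includes all the values observed. However, each round drew its libraries once, with replacement, whereas each observed value is a mean over 35 splits of the controls. The range is therefore not a like comparison and does not decide whether the observed values exceed chance. Genes are not independent replicates, and no p is given. Chlorpyrifos and acrylamide at IC5 shared 1467 higher and 1452 lower genes, where independent calls would give 409 and 422.5, and 153 genes were called in opposite directions. This pair had the highest r at IC5. Methyl mercury and valproic acid, with the lowest, shared 471 and 409 (141.5 and 150.8 if independent) with 338 opposite, and acrylamide and valproic acid shared 1424 and 1406 (597 and 535) with 675 opposite, the most of the 10 pairs. At IC20/100 the 3 compounds dissolved in DMSO shared 672 higher and 760 lower genes, where independent calls would give 8.0 and 8.1. Of these, 241 and 320 were also called the same way in all 3 of these compounds at IC5. Of the same 672 and 760 genes, 566 and 579 were called the same way at acrylamide IC5, and 444 and 425 at valproic acid IC5. Those 2 groups called 41.97 and 26.85% of all genes tested, both directions together. The shared counts were 4 and 0 (by limma) at acrylamide IC20/100, which had 12 called genes in all, and 151 and 176 at valproic acid IC20/100. Since all these comparisons use the same controls, shared calls also carry the chance values of those controls, and how many calls this adds was not determined.

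To determine where the exposed cultures lay between progenitors and controls, a differentiation score was computed from 454 genes higher and 423 lower in controls than in NPC by at least 4-fold. The gene sets came from NPC and the odd-numbered controls, and each exposed group was compared with the 4 even-numbered ones. NPC scored -2.93 ± 0.14 and these 4 controls 2.41 ± 0.08 (SD). Acrylamide IC5 scored 1.34 ± 0.07, or 79.9% of the way from NPC to controls, with all 8 libraries below the control mean (exact permutation p = 0.00202, 2-sided, the smallest the 495 splits allow; adjusted p = 0.00289). Valproic acid IC5 scored 1.82 ± 0.11 (89.0%), chlorpyrifos 1.96 ± 0.09 at IC5 and 2.06 ± 0.09 at IC20/100, and fluoxetine 2.08 ± 0.09 and 2.04 ± 0.05. Methyl mercury IC20/100 scored 2.12 ± 0.05. Each of these had the same exact p as acrylamide IC5. Valproic acid IC20/100 scored 2.09 ± 0.23 (exact p = 0.0323, adjusted p = 0.0404), with replicates 4 and 8 at 1.71 and 1.72 and the other 6 from 2.15 to 2.28. Acrylamide IC20/100, 2.29 ± 0.09 (exact p = 0.0505, adjusted p = 0.0561), and methyl mercury IC5, 2.25 ± 0.17 (exact p = 0.0929, adjusted p = 0.0929), did not pass. The score measures position along genes chosen from this experiment only. Genes of the stress-response and cell cycle lists can be among them. ATF5 (2.16 ± 0.09) and RRM2 (-2.63 ± 0.10) differed at least 4-fold between all 8 controls and NPC, and both moved the opposite way at acrylamide IC5. How far such genes account for the lower scores was not tested.

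**Figure D4:**
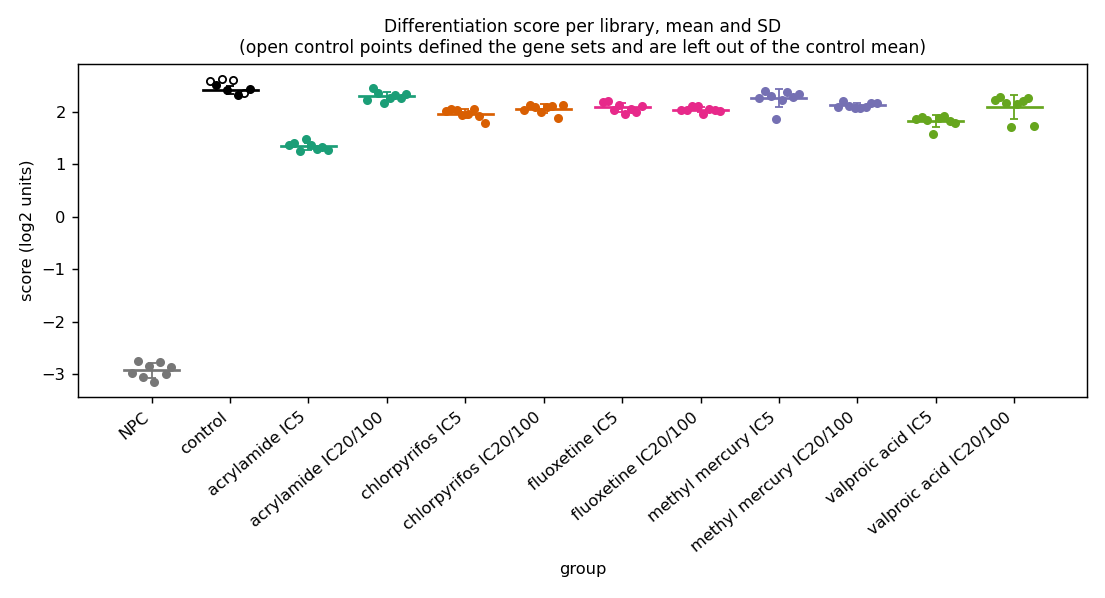
Differentiation score (log2 units) of each library in the 12 groups, with the mean (line) and SD (bar). Open points are the odd-numbered controls, which defined the gene sets and are left out of the control mean. The means were -2.93 for NPC, 2.41 for the 4 even-numbered controls and 1.34 for acrylamide IC5, and all 8 controls lay between 2.31 and 2.62.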

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

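The tests of sequencing run, depth and concentration in the first pattern, and those of GDF1 with CERS1 and of methyl mercury IC20/100 replicate 8, were chosen only after the result was seen, while the split by vehicle was planned.

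At IC20/100, 288 genes separated the compounds dissolved in DMSO (chlorpyrifos, fluoxetine, methyl mercury) from both compounds dissolved in medium in all 6 pairwise contrasts, 65 higher and 223 lower in the DMSO groups, while the 9 other ways to split the compounds gave 0 genes by limma at the adjusted threshold. Both medium groups differed little from controls there (12 genes for acrylamide, 511 for valproic acid), which by itself favours this split over the others. At IC5 the split by vehicle gave 450 genes, and the others gave 26 to 164, so there the compounds also separated in other ways. Over all genes the DMSO groups together had 1735 higher and 1823 lower than the medium groups at IC20/100, so the imbalance among the 288 was not seen over all called genes. Among the lower genes were SLC7A11 (-1.73 ± 0.08) and ATF5 (-1.54 ± 0.07), and 18 of 24 stress-response genes were lower in the DMSO groups (adjusted p = 1.77e-06 with an estimated correlation). Other lists that passed both ways were also lower, namely p53 targets (13 of 20), progenitor (11 of 24, 3 higher), axon guidance (14 of 30, 3 higher), transmitter identity (7 of 21, 1 higher), WNT pathway (5 of 25), mesenchymal and pericyte (7 of 14) and oligodendrocyte lineage genes (3 of 9, 1 higher). Whether the mix of cell types differed was not tested. Sequencing run is argued against as the whole cause by the design, since every run held libraries of every group. Of genes chosen without a run, at least 96.5% had the same direction in that run. With depth as a term 282 of the 288 passed, but these genes were chosen for passing the same contrasts in the same libraries, so that count adds little. Mean recovered reads at IC20/100 overlapped, with 17.0 and 19.2 M in the medium groups and 18.9, 17.6 and 19.0 M in the DMSO groups. An effect of the vehicle is a candidate explanation, but each vehicle comes with its own compounds, whether the controls held DMSO is not given in the sources used here, and acrylamide IC5 and valproic acid at both concentrations, given in medium, also had lower stress-response genes than controls. A response to the compounds that grows with concentration stays open. Of 156 genes chosen from odd-numbered libraries, 63.5% (chlorpyrifos), 45.5% (fluoxetine) and 34% (methyl mercury) lay further from the medium groups at IC5 in the even-numbered ones. The median log2 shifts were 0.034, -0.034 and -0.124, where positive means further. Only chlorpyrifos had most of these genes further, and only 10 genes in all differed between its concentrations. Among the 288 genes, 103 lay nearer at IC5 for methyl mercury, 41 for fluoxetine and 2 for chlorpyrifos (17, 44 and 0 further). This count is biased towards nearer because the genes were chosen at IC20/100.

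GDF1 had a median log2 fold change of 3.26 in the exposed groups. It overlaps CERS1 on the same strand, and over 96 libraries the within-group deviations of both genes were opposed (Pearson r = -0.765, Spearman rho = -0.833, permutation p = 1e-05 for each, the smallest the permutations can give; r = -0.809 without the 2 farthest libraries). The median log2 fold change of their sum was 0.29 (-0.02 to 0.55). In controls GDF1 ranged from 0 to 393, with 3 libraries at 0. Reads shared with CERS1 are a candidate explanation, and a biological change of GDF1 was not tested apart from it.

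Methyl mercury IC20/100 replicate 8 stood apart. Its deposited total was 20.95 M (18.4 to 18.8 M in the other 7 libraries), with 12.6% of reads in ribosomal protein genes (6.24 to 7.08) and 6.82% in the 10 most abundant genes (5.12 to 5.58). NES was 22110 (15850 to 17190), DCX 13390 (24540 to 27330), MAP2 9957 (15910 to 17610) and S100B 39.9 (13.9 to 25.2). A wrong size factor alone is argued against, because the SD of its deviations after centring was 0.717 against at most 0.498 in 87 other day 10 libraries, while its deviations fell with gene length (rho = -0.376 across genes; -0.108 to 0.175 in the others), which is consistent with a length bias such as RNA degradation may give. GC content was related too (rho = 0.336; -0.251 to 0.186 in the others), and no biological explanation was tested, since the design names none for 1 library.

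Each other value below was far from the other 7 libraries of its group by Dixon's criterion. Of 179 such tests 22 passed, where chance gives about 1 in 20, or 8.9. Genes with at least 1 read numbered 24580 in fluoxetine IC5 replicate 6 (25910 to 26990 in the others), 24150 in methyl mercury IC20/100 replicate 6 (25850 to 26760) and 24910 in valproic acid IC20/100 replicate 8 (26290 to 27120). In methyl mercury IC5 replicate 4 the 10 most abundant genes took 5.14% (5.38 to 5.52), the differentiation score was 1.86 (2.22 to 2.39) and NES was 16670 (13440 to 14750). The score of valproic acid IC5 replicate 4 was 1.57 (1.78 to 1.91). NES was 18820 in chlorpyrifos IC5 replicate 8 (16930 to 17580), and MKI67 was 5410 in valproic acid IC20/100 replicate 8 (3302 to 4277). DCX was 29360 in chlorpyrifos IC20/100 replicate 4 (25140 to 27120) and 28690 in valproic acid IC5 replicate 1 (25590 to 26860). GFAP was 34.5 in NPC replicate 6 (2.12 to 8.94), 49.3 in acrylamide IC5 replicate 5 (3.93 to 11.4) and 115.7 in fluoxetine IC20/100 replicate 4 (6.63 to 32.0). S100B was 14.3 in valproic acid IC20/100 replicate 2 (21.1 to 26.7).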

How the results depend on the processing

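The tests with edgeR, with other pseudocounts, and without NPC replicate 6, methyl mercury IC20/100 replicate 8, methyl mercury or valproic acid IC5 replicate 4, or valproic acid IC20/100 replicates 4 and 8 were chosen only after the data were seen. Of 24503 values of named genes under the alternatives, 22837 stayed on their side of the threshold, 1640 no longer passed, 26 newly passed and 0 called values changed sign. Most of these genes were named because they were called in the same data, so a large share that stays was largely fixed in advance. Genes that an alternative fit did not keep were left out of these values. Differentiation had 105 values with all 12 groups in the fit and 94 without NPC replicate 6. The filter still asked for 8 libraries there, so genes that reached its value only in NPC were no longer tested. Against a 1.2-fold change 607 of 1201 values no longer passed, and with only the 2 compared groups in the fit 238 of 1063. The larger direction among the called genes changed in 31 of 325 counts, as for differentiation (6867 higher and 6739 lower with all 12 groups in the fit) and methyl mercury IC20/100 (1341 and 1355 without its replicate 8, 92 and 259 with only the 2 compared groups in the fit, 42 and 140 against a 1.2-fold change). It changed most often for chlorpyrifos IC20/100, nearly balanced at 1422 higher and 1414 lower in the main fit. That comparison gave 1184 and 1216 with no run term, and 1091 and 1234 with only the 2 compared groups in the fit. Counts of called genes stayed within 1.5 times under TMM scaling, a replicate block, a fragment size term, both pseudocounts, and without NPC replicate 6 (12177 genes for differentiation) or replicate 4 of methyl mercury or valproic acid IC5 (751 genes for fluoxetine between concentrations without the latter). The number of groups past the threshold in the differentiation score, 8 of 10, was 7 with the odd and even controls swapped or run not removed and 10 with 2-fold sets or all controls, and the Spearman form of the shared response gave 0.291. For the gene lists of the differentiation comparison the block took the place of run, because both could not be fitted.

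The test against a 1.2-fold change, a stricter test by construction, gave 8330 genes for differentiation, 2802 for acrylamide IC5 and 0 by limma for IC20/100 (1324 with an unadjusted p under 0.05 against no change, 25 by DESeq2, 8 by edgeR), 410 and 231 for chlorpyrifos, 226 and 227 for fluoxetine, 144 and 182 for methyl mercury, and 929 and 0 for valproic acid (2832 unadjusted at IC20/100, 691 by DESeq2 and 535 by edgeR against no change). Between concentrations it gave 2610 (acrylamide), 1 (chlorpyrifos), 56 (fluoxetine), 21 (methyl mercury) and 467 (valproic acid). For the following the cause was not tested. Acrylamide IC20/100, 12 genes, gave 25 by DESeq2, 7 with no low-value filter and 6 with no run term. Valproic acid IC20/100, 511, gave 329 with no run term. Chlorpyrifos between concentrations, 10, gave 63 by DESeq2, 16 by edgeR and 5 with no run term. With only the 2 compared groups in the fit, which leaves fewer libraries to estimate the spread, the counts were 0 by limma (acrylamide IC20/100), 351 (methyl mercury IC20/100), 22 (valproic acid IC20/100), and between concentrations 2 (chlorpyrifos), 450 (fluoxetine) and 27 (methyl mercury). Fits of the same size gave 2628 for fluoxetine IC20/100 (2904 in the main fit) and 2017 for methyl mercury IC5 (2197). The number of libraries alone therefore does not account for the drop of methyl mercury IC20/100 from 3185. Replicate 8 of that group stood apart. Without methyl mercury IC20/100 replicate 8 the counts were 27 (acrylamide IC20/100), 925 (valproic acid IC20/100), 27 (chlorpyrifos between concentrations) and 1175 (fluoxetine between concentrations). The other 11 of 15 counts in that fit stayed within 1.5 times. Among them fluoxetine IC5 had 1546 genes higher and 1538 lower, against 1102 and 1197 in the main fit. Without valproic acid IC20/100 replicates 4 and 8 that group gave 93.

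Leaving out each control in turn gave 11993 to 12528 genes for differentiation, 8046 to 8459 and 6 to 13 for acrylamide (IC5, IC20/100), 3480 to 4046 and 2414 to 2929 for chlorpyrifos, 1972 to 2387 and 2468 to 2964 for fluoxetine, 1868 to 2222 and 2711 to 3319 for methyl mercury, and 4957 to 5414 and 320 to 670 for valproic acid. Without 1 control, genes that reached the filter value only in controls were no longer tested for differentiation, which by itself lowers its counts. Acrylamide IC20/100 gave 7, 6 and 6 without control replicate 1, 4 or 6, and valproic acid IC20/100 gave 320 without replicate 1. A 2-fold limit, stricter by construction, gave a median of 461.5 genes for the compound pairs at IC5. Of 308 list tests 61 passed with an estimated correlation and 198 with fry, which tests another question, against 108. The shared response, 0.283, was 0.478 with the same 8 controls for both groups, which adds their shared chance values, and 0.476 on genes called in either group. Those genes were called against the same 8 controls in the same data, so the value of 0.476 is not independent support. Depth limits genes with values under about 10.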

Other observations

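The test of each count against other splits of the libraries was planned, and the tests of single genes that jump between libraries were chosen only after the result was seen.

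Fluoxetine and methyl mercury at IC5 were also accompanied by lower glial and regional identity transcripts. Of 9 oligodendrocyte lineage genes 4 fell with methyl mercury and 0 rose (camera adjusted p = 0.000486, and 0.00153 with an estimated correlation), CSPG4, a proteoglycan of oligodendrocyte precursors, by 0.88 on the log2 scale (SE 0.13). Astrocyte genes fell, 4 of 21 with 0 up for methyl mercury (camera adjusted p = 0.0127, and 0.016 with an estimated correlation) and 4 with 1 up for fluoxetine (camera adjusted p = 0.0367, and 0.0399 with an estimated correlation), with FGFR3, a growth factor receptor, at -0.33 ± 0.04 and -0.54 ± 0.04. Regional identity genes fell, 3 of 17 and 4 of 17 (camera adjusted p = 0.0148 and 0.0117, and 0.0308 and 0.0262 with an estimated correlation). Of 26 neurogenesis genes 8 fell and 3 rose with methyl mercury (13 and 4 adjusted over the list alone; camera adjusted p = 0.0047, and 0.0284 with an estimated correlation). VGF, a secreted neuropeptide precursor, fell with fluoxetine (-0.86 ± 0.08) and methyl mercury (-0.67 ± 0.08), and BDNF, a neurotrophin, by 0.88 and 0.81 on the log2 scale. All genes named here moved the same way in all 6 runs.

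Activity-regulated genes were lower in unexposed day 10 controls than in NPC, 12 of 15 with 1 up (13 and 1 adjusted over the list alone; camera adjusted p = 0.00326, and 0.0706 with an estimated correlation). EGR1, an immediate early transcription factor, fell from 1387 ± 84.6 to 68.7 ± 7.23 (-4.29 ± 0.06, adjusted p = 3.27e-13). Heat shock genes fell, 11 of 13 with 2 up (camera adjusted p = 0.00172, and 0.0904 with an estimated correlation), HSPH1 at -1.35 ± 0.11, and 13 of 20 p53 targets rose with 3 down (camera adjusted p = 0.0134, and 0.339 with an estimated correlation), CDKN1A by 2.31 ± 0.13. All 5 measured vascular, choroid plexus and microglia genes fell (camera adjusted p = 0.0222, and 0.0928 with an estimated correlation), KDR from 107 ± 23.5 to 5.25 ± 3.17. UNC5B, a netrin receptor, fell from 632 ± 148 to 170.4 ± 19.8 at chlorpyrifos IC5 (-1.85 ± 0.12) and to 182.5 ± 22.3 at IC20/100 (-1.74 ± 0.12), while the axon guidance list at IC5, 11 down and 3 up of 30, had a camera adjusted p of 0.0256, and 0.238 with an estimated correlation.

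Some genes jumped between libraries of a group. In all, 477 genes reached at least 10 times their group median in at least 1 library, with medians under 10 counted as 10. CACNA1I, a calcium channel gene chosen after its values were seen, was between 2762 and 3485 in 5 of 88 day 10 libraries, from 4 groups, and at most 111.8 in the rest (median 63.3).

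Each count of called genes was set against other splits of the same 16 libraries, 100 splits with the real one included, in fits of these libraries only. The splits exchange technical replicates of 1 experiment, so they cannot exclude chance differences between the cultures behind each group. They ask only whether another division of the libraries calls as many genes. The real split alone reached its count, 1 of 100 and the lowest share possible, for differentiation (12770 genes, highest other 10008) and acrylamide IC5 (8228, 3879). The same held for chlorpyrifos IC5 (3724, 3) and IC20/100 (2325, 4), and fluoxetine IC5 (1938, 985) and IC20/100 (2628, 1). It also held for methyl mercury IC5 (2017, 6) and IC20/100 (351, 2), and valproic acid IC5 (5590, 2410) and IC20/100 (22, 1). Between concentrations this held for acrylamide (7824, 1), fluoxetine (450, 4) and valproic acid (3016, 2). The real count of methyl mercury was also the highest, but close to that of a split that exchanged 3 libraries of each group (27, 18). No conclusion is drawn from it. For chlorpyrifos between concentrations 4 of 100 splits gave as many as the real 2 genes (highest other 4), too weak to count against chance among so many such tests. For acrylamide IC20/100 the real count in the fit of 16 libraries was 0 by limma, which 100 of 100 splits reach, so this says nothing of the 12 genes of the fit of all day 10 libraries (highest other 2; 1324 genes with an unadjusted p under 0.05 in the fit of 88 libraries, 25 by DESeq2 and 8 by edgeR). Between compounds at IC5 the real split alone reached its count for acrylamide against chlorpyrifos (5198, 2180), fluoxetine (6781, 3094), methyl mercury (7457, 5173) and valproic acid (7478, 1). So it did for chlorpyrifos against fluoxetine (916, 3), methyl mercury (1919, 8) and valproic acid (4251, 1506). The remaining pairs were fluoxetine against methyl mercury (1549, 10) and valproic acid (4455, 3), and methyl mercury against valproic acid (5079, 1041), with the same result. Highest other counts of 985 or more came from splits that exchanged 1 library of each group.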
